A study of Mus musculus with 4 samples.

How the data were processed

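Single-cell RNA libraries were made with 10x Chromium 3' v3.1 chemistry from dissected telencephalic midline, with about 14400 cells loaded and 9000 targeted per library, per the labels. The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode, made with Cell Ranger 7.1.0 on mm10 per the file headers and the submitters' processing notes; the annotation is not given in the sources used here. The matrices held 21937 features, among them a tdTomato sequence, and only barcodes with at least 500 UMIs, so they had been filtered for cells before deposit. Sample titles give the ages as E11 and E14 and the series text as E11.5 and E14.5; the latter are used. Groups were taken from the labels, with 1 library each, so no replicates exist.

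Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept, which removed 616, 1084, 775 and 691 barcodes in the order E11.5 control, E11.5 gof, E14.5 control and E14.5 gof. Scrublet's own threshold called 0, 1, 431 and 361 doublets, so it did not work at E11.5, and the planned rule was used at both ages: per library, the barcodes with the highest Scrublet scores were removed, at a rate of 0.8% per 1000 barcodes (459, 602, 492 and 314 barcodes). The 25417 kept cells were clustered together with scanpy 1.11.5 and igraph 0.11.9 in Python 3.11.15, with seed 1 and a single thread. The clustering used log-normalised counts, 3000 highly variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 1. Variable genes were chosen with the library as batch, but no correction between libraries was applied. All marker and list genes were left out of the clustering, as were mitochondrial, ribosomal, haemoglobin and Y-linked genes, so that marker levels did not enter the clusters directly. Clusters were still named from marker levels, so class sizes depend on these levels.

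Clusters were named from 16 marker sets fixed before the data were examined. A name needed a mean marker log2 fold of at least 0.5 over the mean of the other clusters, at least 3 markers in 10% or more of the cells and at least 2-fold up, and no fewer own markers than those of any other class among the 10 leading genes (genes in at least 25% of the cluster). A cluster with a median UMI count over 3 times lower than its library's needed an own marker among them, and a cluster led by Fgf8 or Fgf17 was not called hem-like. These naming limits, the Fgf8 and Fgf17 exclusion and the number of variable genes were set after the clusters' leading genes, scores and sizes per library had been seen, and several versions were considered. The exclusion keeps cluster 1 out of the hem-like class, the score limit keeps cluster 29 unnamed, and cluster 10 falls short of both the score and the number of markers. A histone- and haemoglobin-led cluster (cluster 16) is among the pallial progenitor-like cells. Neural cells are all cells outside the non-neural classes, unnamed clusters included. Other class names are a rebuilt reading of the clusters, not the authors' annotation.

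Shares of kept cells have exact Clopper-Pearson intervals. Counts were summed over the cells of a library or class, scaled to CPM and given exact Poisson intervals; both cover counting error only, and no p-value or standard error was made from cells. Log2 ratios used a pseudocount of 1 CPM, except the marker scores for naming, which used a larger one. For 21 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 10 CPM in either library, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A member counts as higher or lower if it differs by at least 1.5-fold with separate 95% intervals, which compares 2 libraries and not the genotypes. On simulated libraries of the real sizes, this rule found 100% of 2-fold and 4-fold and 0% of 1.25-fold differences, and 0 of 7876 unchanged genes among the 8076 of the E11.5 comparison and 0 of 9248 among the 9448 at E14.5. A 1.25-fold difference cannot pass a limit of 1.5-fold. With 1 pool per group the variation between pools is unknown, so these shares are no rate of false calls between genotypes. Ambient RNA was not removed. For shares of cells with a UMI, cells were thinned to 3000 UMIs, leaving out 103, 654, 275 and 264 cells. The symbols of 67 features occur more than once and were told apart by gene ID.

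Named genes follow a rule fixed before the data were examined. It takes the 10 highest and 10 lowest log2 ratios of the whole library at each age among genes of at least 50 CPM in either library, without haemoglobin, mitochondrial, ribosomal, Y-linked and clone-named genes. It adds the 8 genes most strongly higher and the 8 lower at both ages within a class, the 2 highest and 2 lowest members of each list, a set of 8 preset genes, and the 5 highest and 5 lowest between ages. For classes, it was written for hem-like and Cajal-Retzius-like cells; it was applied to hem-like or choroid plexus-like cells joined and to tdTomato-positive cells, since hem-like cells at E14.5 and Cajal-Retzius-like cells of the E14.5 gof library were too few. tdTomato itself was left out. The tdTomato-positive level and its limit of 2 UMIs, the joined class, the minimum of 100 cells per library for comparing a class, the clusters described one by one, and list members and genes named beyond the rule were chosen after their values had been seen.

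TMM factors came from edgeR 4.0.16 in R 4.3.3, used only as an alternative scaling. Alternatives covered the barcode filters, doublet removal, resolution, clustering genes, clustering per library, naming limits, denominator, a gate on markers per cell, scaling, pseudocount, expression filter, mean of cells, all barcodes, neural cells and tdTomato-positive cells. Tables and figures used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene coordinates come from GENCODE M21 on GRCm38, the assembly named mm10 by the submitters, matched by gene ID.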

Results

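Cells from the dorsal midline of the mouse telencephalon, around the cortical hem, were profiled by droplet single-cell RNA sequencing at E11.5 and E14.5. The hem is a signalling centre at the edge of the cortex that secretes Wnt and BMP proteins; Cajal-Retzius neurons arise from it and the choroid plexus forms beside it. In both genotypes Lmx1aCre switched on tdTomato from the Ai9 reporter, and in the gof genotype the Cre also met an allele labelled b-cat gof, introduced to keep canonical Wnt signalling on in hem progenitors. There were 4 libraries, 1 for each age and genotype, each from a pool of 5 male embryos at E11.5 or 3 at E14.5. The comparisons ask how hem cells and their offspring differ between the gof and control libraries at each age.

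The E11.5 control and gof libraries held 7578 and 8677 barcodes with 78732126 and 59594082 UMIs in total, and the E14.5 control and gof libraries held 7844 and 6263 barcodes with 113821989 and 93988703 UMIs. After filtering, 6505, 7008, 6595 and 5309 cells were kept, in the same order, with a median of 8163, 5644, 12874 and 14083 UMIs per cell. Each group was 1 library, so no difference reported here has a replicate check and no test between groups was possible. All intervals are exact 95% intervals, Clopper-Pearson for shares and Poisson for counts, and cover counting error only. Expression is given as summed UMI counts scaled to CPM, and folds and log2 ratios were taken after adding 1 CPM, which understates the difference of weakly expressed genes.

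Ctnnb1, which encodes beta-catenin, was read at 253 CPM in the E11.5 control library and 214 CPM in the gof library, and at 310 and 289 CPM at E14.5. These are counts of the 3' end of the transcript, and the labels do not name the altered part of the gene, so they do not check the allele. The median log2 ratio of all genes was -0.11 at E11.5 and -0.09 at E14.5. On GRCm38, by GENCODE M21, Ctnnb1 (ENSMUSG00000006932) lies on chromosome 9 from 120929216 to 120960507, Axin2 (ENSMUSG00000000142) on chromosome 11 from 108920349 to 108950783, and Lef1 (ENSMUSG00000027985) on chromosome 3 from 131110471 to 131224356. Lmx1a (ENSMUSG00000026686) lies on chromosome 1 from 167689237 to 167848741, Wnt3a (ENSMUSG00000009900) on chromosome 11 from 59248033 to 59290752, and Ttr (ENSMUSG00000061808) on chromosome 18 from 20665280 to 20674321. Trp73 (ENSMUSG00000029026) lies on chromosome 4 from 154056253 to 154140208, and Reln (ENSMUSG00000042453) on chromosome 5 from 21884454 to 22344702. All of these are protein-coding genes, and the values are totals over each gene.

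At E11.5, cells carrying the reporter showed higher levels of canonical Wnt targets in the gof library. Among cells with at least 2 tdTomato UMIs, Notum, a secreted enzyme that inactivates Wnt proteins, was read at 71.5 CPM in gof and 0.868 CPM in control cells. Dkk1, a secreted Wnt antagonist, was read at 55.7 and 0.543 CPM, and Wif1, which binds Wnt proteins outside the cell, at 111 and 7.71 CPM. Axin2, a negative regulator that is itself a Wnt target, was at 188 and 122 CPM, and Lef1, a transcription factor that partners beta-catenin, at 180 and 81.9 CPM. Of the 13 measured Wnt targets, 10 were higher and 0 lower by at least 1.5-fold with separate intervals, and their median log2 ratio of 1.13 lay at the 100th percentile of 10000 random lists matched on expression. These values come from 556 control and 292 gof cells, 8.55% (7.88 to 9.25) and 4.17% (3.71 to 4.66) of kept cells, where non-neural cells gave 0.733% and 0.855%. Median depth of the tdTomato-positive cells differed too, at 13454 and 9758.5 UMIs, against 8178 and 6633 UMIs in non-neural cells.

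In whole E11.5 libraries the difference in Wnt targets was smaller. Notum (log2 ratio 2.62), Dkk1 (1.96), Wif1 and Nkd1, an intracellular antagonist of the pathway, were higher, and none of the 12 measured targets was lower. The list's median was 0.10, at the 98.7th percentile, and turned to -0.23 when only genes of at least 50 CPM were read. Axin2 was at 68.4 CPM in control and 62.4 CPM in gof, and Lef1 at 89.5 and 85.8 CPM. Hem identity genes were lower as a group, with a median of -0.43 (0.03rd percentile) and 3 of 10 lower, namely Lmx1a, the hem transcription factor that drives the Cre (31.7 against 19.6 CPM), the Wnt co-agonist Rspo2 (217 against 127 CPM) and Bmp6. In neural cells alone, which leave out the non-neural classes more frequent in gof, the hem median was -0.20 and none of the 10 genes was past the limits. Wnt3a, the ligand that marks the hem, was at 15.5 and 12.8 CPM.

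The cell classes of the E11.5 libraries differed modestly for the hem and its neurons and more for cells from outside the brain. Hem-like cells made up 9.04% (8.35 to 9.76) of control and 6.38% (5.82 to 6.98) of gof cells, and Cajal-Retzius-like cells 10.9% (10.1 to 11.7) and 14.54% (13.7 to 15.4). Mesenchymal or meningeal-like cells were at 8.58% and 17.1%, and all non-neural cells at 12.6% and 23.4%. Diencephalic-like cells were at 13.99% and 10.9%. Unnamed clusters held 52.6% of control and 43.6% of gof cells. They include cluster 1, led by Fgf17 and Fgf8 and high in hem markers, with 11.7% and 8.62%, and cluster 8 with 2.91% and 0.186%. Cluster 8 had a median of 24063.5 UMIs, against 8163 in the E11.5 control library, and was named erythroid-like at a resolution of 2. It held 54 tdTomato-positive control cells and 1 gof cell, 9.71% and 0.342% of them. Whether it is made up of doublets was not tested. The direction of both the hem-like and the Cajal-Retzius-like share depended on the processing. Requiring at least 2000 genes and at most 5% mitochondrial UMIs gave log2 ratios of 0.10 for hem-like and -0.38 for Cajal-Retzius-like cells, and clustering each library on its own gave 0.47 and -0.02, against -0.50 and 0.42. In the latter setting 527 control and 0 gof cells took the choroid plexus name, and the hem-like and choroid plexus-like shares joined, 16.6% and 11.8%, kept the direction (-0.49). The sizes of the classes moved too. At a resolution of 2 hem-like cells made up 18.6% and 12.2%, and Cajal-Retzius-like cells 4.78% and 5.02%, with 1067 cells of a cluster led by Uncx and Ebf2, which also lead cluster 7, the Cajal-Retzius-like cluster of this age, named intermediate progenitor-like. Cajal-Retzius-like shares were also lower with marker genes kept in the clustering (4.81% and 5.25%) and with 2000 variable genes (4.72% and 4.89%).

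Cluster 10 held 351 of the E11.5 gof cells, 5.01% (4.51 to 5.55), and 1 control cell. Its gof cells carried tdTomato at 165 CPM (150 to 181) and made up 36.0% of the tdTomato-positive gof cells. Wnt targets, which were left out of the clustering, were high in it: Sp5, a transcription factor that acts downstream of beta-catenin, at 498 CPM, Nkd1 at 351 CPM, Lef1 at 313 CPM, Axin2 at 279 CPM and Notum at 174 CPM. Trp73, a transcription factor of Cajal-Retzius neurons, was at 2.72 CPM, and Ttr, the thyroid hormone carrier made by choroid plexus, at 17.9 CPM. The cluster's markers did not reach the level required for a name, the nearest class being hem.

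**Figure D1:**
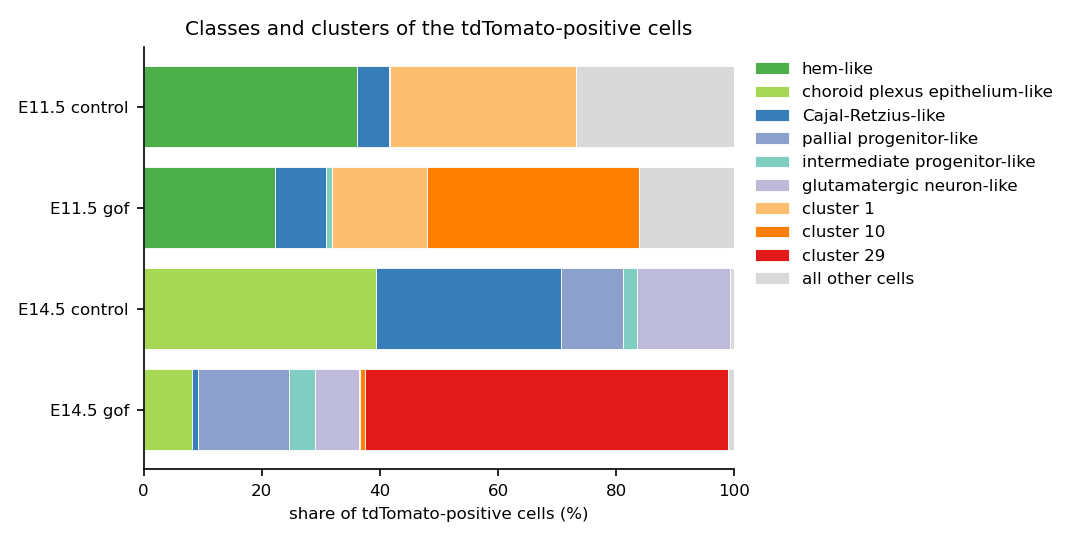
Shares (%) of tdTomato-positive cells, those with at least 2 tdTomato UMIs, that fall into each class or cluster, with 1 bar per library. Cluster 10 holds 36.0% of them in the E11.5 gof library, and cluster 29 holds 61.5% in the E14.5 gof library.

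Cortical patterning genes were lower in the E11.5 gof library. The median of the pallial and hippocampal patterning list was -0.52 (0th percentile), with 7 of 16 measured genes lower, among them Dmrt3 (-1.06), Nfix (-0.90) and Emx2, transcription factors of the medial cortex. Hes5, a Notch effector that maintains progenitors, was 7.02-fold lower (47.4 against 339 CPM), and Id1, a BMP target, 2.88-fold lower. In tdTomato-positive cells Hes5 was 4.56-fold lower (72.9 against 336 CPM) and Id1 2.50-fold. Neither difference was thus larger in cells carrying the reporter than in the whole library. BMP ligands and targets had a median of -0.27 with 5 of 13 lower, and the Notch pathway a median of -0.24 with Hes5, Hey1 and Nrarp lower. In neural cells alone, without the non-neural classes that were more frequent in gof, the patterning median was -0.27 with Dmrt3 and Nfix lower.

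Among the other lists at E11.5, glutamatergic neuron genes had a median of 0.31 (99.99th percentile), with Crym and Mef2c higher and Fezf2 among those lower. Neurogenic intermediate progenitor genes had a median of 0.13 with Gadd45g and Insm1 higher, and pan-neuronal genes 0.16 with none past the limits. Cajal-Retzius identity genes had a median of -0.01 with Ebf3 higher, but 0.40 with 5 of 10 higher in neural cells alone. Choroid plexus identity genes had a median of -0.25 with Ttr lower (238 against 109 CPM). FGF pathway genes had a median of 0.13, with Spry2, an inhibitor induced by FGF, Etv1 and Dusp6 higher and Fgf17 lower. Wnt ligands and R-spondins, most of which are also in the hem list, had a median of -0.38 with Rspo2 lower. Secreted Wnt antagonists had one of -0.11 with Frzb higher, Shh pathway genes -0.33 with Boc lower, and ciliogenesis genes -0.43 with Rfx2 and Rfx4 lower. S phase genes had a median of -0.28 (3 of 40 lower), G2 and M phase genes -0.19 (2 of 50 lower), cell cycle inhibitors and p53 targets -0.01, hypoxia and glycolysis genes -0.07 with Vegfa higher, and cell adhesion and junction genes -0.18 with Jup higher and Cdh4 and Cdh6 lower. Dissociation and stress genes, a sign of handling, had a median of 0.38 with Junb, Egr1, Ier3 and Socs3 higher, and -0.16 in neural cells alone.

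Among genes of at least 50 CPM, those with the highest ratios in the whole E11.5 gof library were Osbpl7 (6.38-fold), Ankrd33b, Peak1, Rpgrip1, Pdgfrl, Crabp1, Col3a1 (3.02-fold), Pbld1, S100a6 and Tex14. Col3a1, a collagen, and Crabp1, S100a6 and Pdgfrl are expressed in mesenchyme, the class with the larger share in this library. The lowest, after Hes5, were the histone genes H1f5 (4.57-fold lower), Hist1h2ap and H1f4, and Id1, Cadps, Nckap5, Ttr, Rgma and Tenm4. Transcripts of replication-dependent histones carry no poly(A) tail, so their counts also depend on capture.

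At E14.5 markers of Cajal-Retzius neurons, choroid plexus and hem were all lower in the gof library. Reln, the secreted protein by which Cajal-Retzius neurons guide cortical layering, was at 283 CPM (280 to 287) in control and 46.0 CPM (44.6 to 47.5) in gof, and Trp73 at 25.5 CPM (24.6 to 26.6) and 2.03 CPM (1.74 to 2.36). Ttr was at 3163 and 634 CPM, Lmx1a at 54.7 and 19.9 CPM, and Wnt3a at 9.39 and 2.01 CPM. Of the 10 measured Cajal-Retzius identity genes 7 were lower and 0 higher (median -1.24), of the 10 choroid plexus genes 7 were lower and Sostdc1, a secreted antagonist of BMP and Wnt, was higher (median -1.05), and of the 9 hem genes 8 were lower (median -1.41). Each of these medians lay at the 0th percentile of random lists. After thinning every cell to 3000 UMIs, 5.51% (4.96 to 6.10) of control and 0.595% (0.402 to 0.848) of gof cells had a Trp73 UMI, and 9.33% and 1.26% without thinning. In non-neural cells the thinned share was 0 of 111 and 0 of 137 cells, with upper limits of 3.27% and 2.66%. Ttr transcripts were also found in 46.7% of the non-neural cells of the control library and 14.2% of those of the gof library, so part of the Ttr level may be RNA free in the suspension, which was not measured.

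Canonical Wnt targets were higher in the whole E14.5 gof library. Their median was 0.82 (100th percentile), with 7 of 13 higher and 0 lower: Notum (48.9 against 0.464 CPM), Wif1 (132 against 11.2 CPM, 10.9-fold), Nkd1, Sp5, Dkk1, Apcdd1 and the cell cycle gene Ccnd1 (96.4 against 20.6 CPM, 4.50-fold). Axin2 was nearly equal, at 82.5 CPM in control and 83.6 CPM in gof, and Lef1 was at 206 and 175 CPM. The Wnt ligands and R-spondins went the other way, with a median of -1.40 and 5 of 7 lower, among them Rspo2 (4.21-fold lower), Wnt9a and Wnt5a. Most members of this list, these genes included, are also in the hem list, so its median is not a result separate from that of the hem genes.

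In tdTomato-positive cells of E14.5 both groups of genes stood further apart. There 14 of 16 Wnt targets were higher, with a median of 1.99, and Lgr5, a receptor for R-spondins, was lower. Notum was at 190 CPM in gof and 0.656 CPM in control cells, Wif1 at 519 and 15.1 CPM, Nkd1 at 566 and 86.2 CPM, Axin2 at 254 and 147 CPM, and Lef1 at 441 and 194 CPM. Cajal-Retzius genes had a median of -1.66 with 8 of 12 lower, choroid plexus genes -1.90 with 10 of 13 lower, and hem genes -1.79 with 10 of 11 lower. Ciliogenesis genes were lower in 11 of 12 (median -2.29), including Foxj1, the master regulator of motile cilia, at 79.1 CPM in control and 16.2 CPM in gof. FGF pathway genes had a median of 1.011 with Fgf17, Spry2, Etv1 and Etv5 higher, hypoxia and glycolysis genes 0.60 with 7 of 14 higher, glutamatergic neuron genes -0.61 with 7 of 14 lower, and intermediate progenitor genes 0.36 with 4 higher and 3 lower of 12. Kcne2, a potassium channel subunit of choroid plexus, was 31.3-fold lower, Htr2c, its serotonin receptor, 16.1-fold, Reln 14.9-fold and Trp73 14.7-fold. Wnt6, a Wnt ligand, was 52.7-fold higher, Mybpc1, a myosin-binding protein, 37.8-fold and Fgf17 22.7-fold. The tdTomato-positive cells numbered 1105 and 1046, 16.8% (15.9 to 17.7) of control and 19.7% (18.6 to 20.8) of gof cells, and non-neural cells gave 5.74% and 6.76%.

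**Figure D2:**
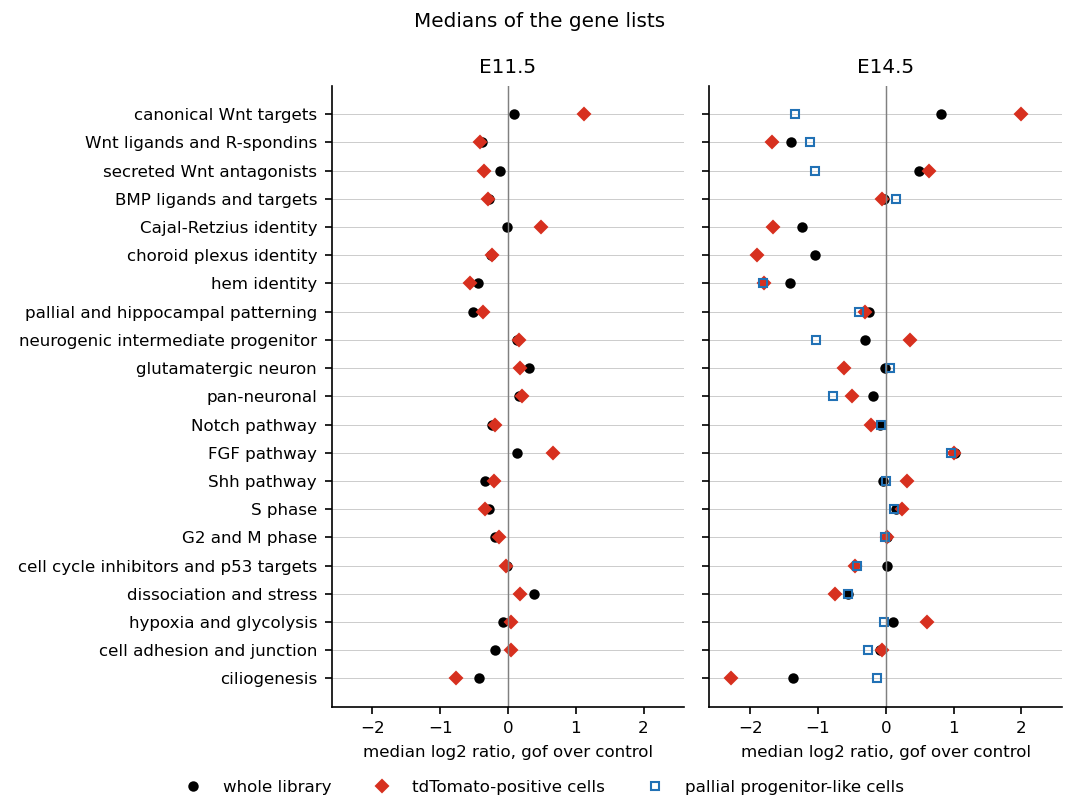
Median log2 ratio (gof over control) of each gene list, on the horizontal axis, at E11.5 and E14.5. Circles are whole libraries, diamonds are tdTomato-positive cells and open squares are pallial progenitor-like cells (E14.5 only). Canonical Wnt targets lie at 1.99 in tdTomato-positive cells of E14.5 and at -1.34 in pallial progenitor-like cells.

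Of the genes of at least 50 CPM that differed the same way at both ages in tdTomato-positive cells, the 8 most strongly higher were Notum, Mybpc1, Dkk1, Wif1, Phlda1, Aspscr1, Nkd1 and Armh4. Phlda1, a regulator of cell survival, had log2 ratios of 2.002 at E11.5 and 2.61 at E14.5. The 8 most strongly lower were Plcl1, Ttr, Trpm3, H1f4, Rspo2, Sox9, Slc6a15 and Prr7. Trpm3, a cation channel of choroid plexus epithelium, had log2 ratios of -1.19 at E11.5 and -1.60 at E14.5, Rspo2 of -1.04 and -2.30, and Sox9, a transcription factor of neural progenitors, of -1.05 and -0.99.

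Of the E14.5 cell classes, the choroid plexus-like and Cajal-Retzius-like had smaller shares in the gof library. Choroid plexus epithelium-like cells made up 8.86% (8.18 to 9.57) of control and 2.02% (1.65 to 2.43) of gof cells, a log2 ratio of -2.14. Cajal-Retzius-like cells made up 7.25% (6.63 to 7.90) and 0.358% (0.216 to 0.558), 478 and 19 cells, a log2 ratio of -4.34. Hem-like cells were only 7 and 3 in this clustering, where cluster 9, named choroid plexus-like, scored 2.68 for that class and 2.49 for hem, so the classes were joined for comparisons within a class (8.96% and 2.07%). At a resolution of 2 most of these cells were named hem-like (418 and 77 cells, 6.34% and 1.45%), and choroid plexus-like cells made up 2.23% and 0.527%, while the joined share was 8.57% and 1.98%. Choroid plexus-like cells were about as few with marker genes kept in the clustering (2.24% and 0.509%), with 2 times the doublets removed (2.12% and 0.552%) and with the stricter barcode filter (2.40% and 0.512%). Intermediate progenitor-like cells were at 8.05% (7.41 to 8.73) and 13.1% (12.2 to 13.99), pallial progenitor-like cells at 45.7% (44.5 to 46.9) and 39.3% (38.0 to 40.7), glutamatergic neuron-like cells at 27.7% in both, GABAergic lineage-like cells at 0.5004% and 0.584%, and non-neural cells at 1.85% and 2.79%. At a resolution of 2 the intermediate progenitor-like share was no longer higher in gof. A cluster led by Unc5d and Synpr, with 468 control and 42 gof cells, then took that name. The other large clusters of that name at this age held 414 control and 433 gof cells, and 89 and 249.

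**Figure D3:**
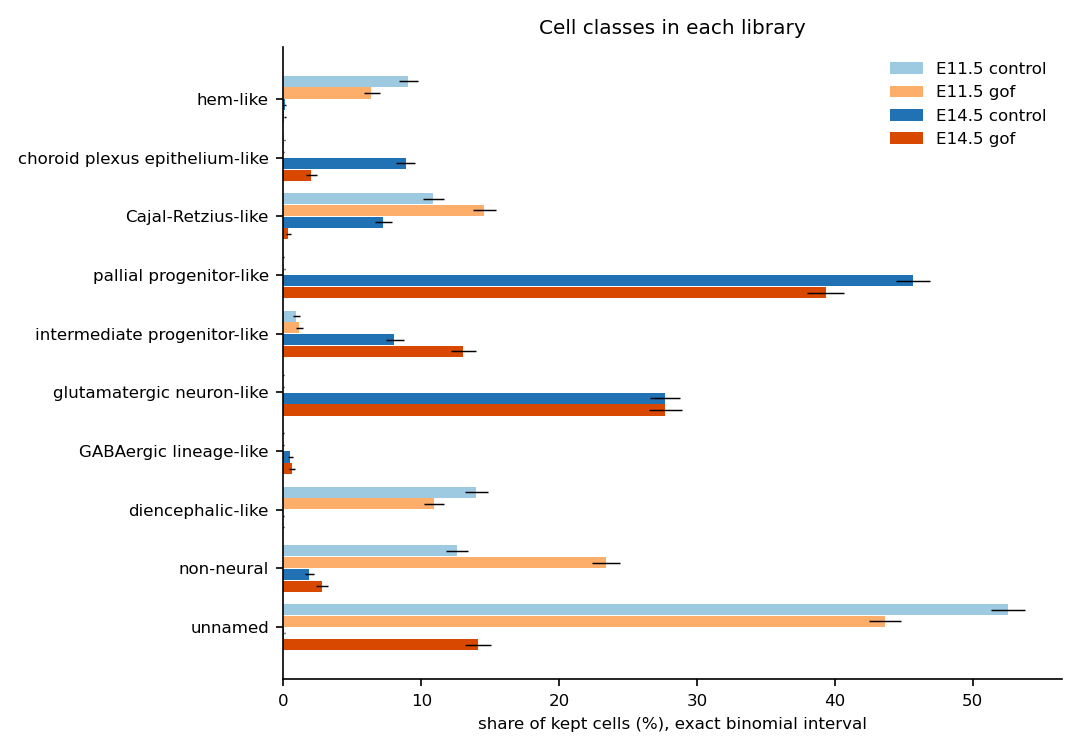
Share of kept cells (%) in each class, with 1 bar per library and exact 95% binomial intervals. Cajal-Retzius-like cells fall from 7.25% in the E14.5 control library to 0.358% in the E14.5 gof library, at the clustering resolution of 1.

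The E14.5 shares depend on where cells of the gof library that clustered apart from control cells are placed. No correction between libraries was applied, so clustering apart does not show that such cells have no counterpart in control. Cluster 29 held 718 cells of the E14.5 gof library, 13.5% (12.6 to 14.47) of it, and 0 cells of the other libraries; the exact upper limit in the E14.5 control library is 0.0559%. It stayed unnamed because its marker score for choroid plexus, the nearest class, was 0.47, under the limit of 0.5 set after the clusters were seen; without that limit the log2 ratio of the choroid plexus-like share was 0.81. At a resolution of 2, a cluster of 439 gof cells led by Asic2, Mybpc1 and Wif1 took the name Cajal-Retzius-like, with none of that class's markers among its 10 leading genes, and the class came to 7.67% of control and 8.55% of gof cells (log2 ratio 0.16). Another cluster of E14.5 gof cells alone, 279 cells led by Pglyrp1 and Notum with tdTomato at 326 CPM, was then named surface epithelium-like. That is a non-neural class, and again none of its markers was among the leading genes. Clustering each library on its own gave -0.27 for the Cajal-Retzius-like and 1.248 for the choroid plexus-like share, and a gate of 3 markers per cell gave -1.39 and 0.07.

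Cells of cluster 29 carried tdTomato at 352 CPM (341 to 363), against 270 CPM in choroid plexus-like and 263 CPM in cluster 23 Cajal-Retzius-like cells of the control library, and made up 61.5% (58.4 to 64.4) of the tdTomato-positive gof cells. In the control library 39.2% of tdTomato-positive cells were choroid plexus-like, in cluster 9, most of which is named hem-like at a resolution of 2, and 31.4% were Cajal-Retzius-like. Wnt targets were high in cluster 29: Nkd1 at 909 CPM, Wif1 at 866 CPM, Lef1 at 659 CPM, Axin2 at 380 CPM and Notum at 315 CPM. Sostdc1 was at 799 CPM, Cdkn1a, an inhibitor of the cell cycle, at 1031 CPM, and Tubb3, the neuronal tubulin, at 1748 CPM. Reln was at 73.7 CPM and Trp73 at 7.12 CPM, 48.0-fold and 43.3-fold below the control Cajal-Retzius-like cells. Of the 13 Cajal-Retzius markers measured, 7 were lower by 4.45-fold or more, and Car10, Cxcr4, Ebf2 and Calb2 differed from it by 2.04-fold or less. With 1 library per group, a cluster of 1 library may reflect that library and not a cell type.

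**Figure D4:**
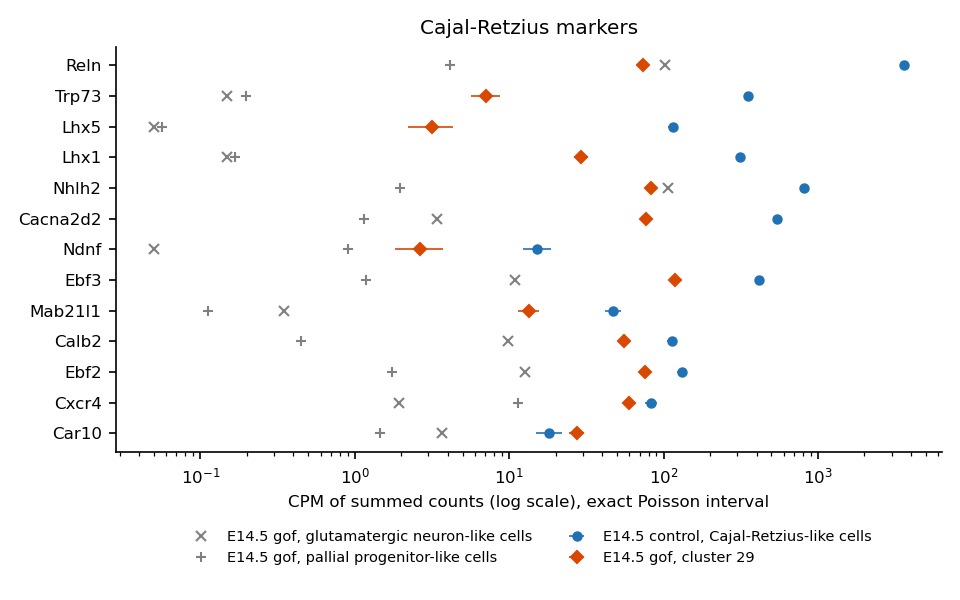
Level of each Cajal-Retzius marker in CPM (log scale) in control Cajal-Retzius-like cells (circles) and gof cluster 29 (diamonds) of E14.5, with exact 95% Poisson intervals, and in gof glutamatergic neuron-like (crosses) and pallial progenitor-like cells (plus signs). Reln lies 48.0-fold and Trp73 43.3-fold lower in cluster 29 than in control, while Car10 lies higher.

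Within the cells named hem-like or choroid plexus-like at E14.5 (591 control and 110 gof), choroid plexus genes were lower in gof, and a part of the proliferation genes was higher. The choroid plexus list had a median of -0.88 with 9 of 15 lower, among them Ttr (31074 against 16097 CPM) and Kcne2 (265 against 24.4 CPM), and the hem list a median of -0.89 with 6 of 11 lower. S phase genes had a median of 0.44 (12 of 40 higher) and G2 and M phase genes of 0.33 (13 of 52 higher), both at the 100th percentile; hypoxia and glycolysis genes had one of 0.78 (9 of 14 higher), and Wnt targets of 0.67 (7 of 13 higher, Notum at 59.6 against 0.609 CPM). At E11.5, in 590 control and 447 gof cells, Wnt targets had a median of 0.41 with Nkd1, Notum, Dkk1 and Wif1 higher, and FGF pathway genes 0.69 with 5 of 7 higher and Fgf17 lower. Pam, an enzyme that matures neuropeptides, Ptn, a growth factor, Higd1a, Zfp503, Tenm2, Pin4, Nkd1 and Fabp7, a lipid-binding protein of radial glia, had higher values at both ages, Fabp7 by only 1.49-fold at E11.5, under the limit used for list members. Ptn was 1.69-fold higher at E11.5 and 4.35-fold at E14.5. H1f4, Pmepa1, an inhibitor of TGF-beta signalling, Elavl4, Plekhg1, Cdv3, Csrnp3, Pak3 and Ldb2 were lower at both ages, Pmepa1 by 1.92-fold and 2.72-fold. Cajal-Retzius-like cells, which at E11.5 include cells named intermediate progenitor-like at a resolution of 2, could be compared at that age, with 708 control and 1019 gof cells, where their identity genes had a median of -0.33 with Cxcr4, a chemokine receptor, lower, and Wnt targets one of 0.16 with Dkk1 higher and Znrf3 lower.

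In pallial progenitor-like cells of E14.5, most of them without the reporter, Wnt targets were lower in gof. Of 11 measured targets 8 were lower and Ccnd1 was higher, with a median of -1.34 (0th percentile). Axin2 was at 85.2 CPM in control and 33.0 CPM in gof, Lef1 at 246 and 98.7 CPM, Nkd1 at 33.7 and 11.3 CPM, and Sp5 at 42.2 and 5.06 CPM. Transcription factors of the hippocampal field were also lower, Zbtb20 at 2021 and 511 CPM and Prox1 at 106 and 20.1 CPM, within a patterning list of median -0.40 (3 of 17 lower). Neurogenic intermediate progenitor genes had a median of -1.03 with 7 of 11 lower, including Neurog2 at 211 and 91.9 CPM and Eomes at 33.7 and 18.5 CPM. Sfrp1, a secreted Wnt antagonist, was higher, at 181 and 470 CPM, as was Etv5, an FGF target, at 4.68 and 25.03 CPM. The class was spread differently over its clusters in the 2 libraries: cluster 17 had 1463 control and 218 gof cells, cluster 19 had 197 and 867, and cluster 20 had 1252 and 970. Sfrp1 is a leading gene of cluster 19, within which 0 of 4 measured secreted Wnt antagonists were higher in gof. This spread may therefore enter the Sfrp1 value of the class. Within clusters 17, 19 and 20 the Wnt target medians were -0.98, -0.70 and -1.28. Those of the intermediate progenitor genes were -0.91, -0.42 and -0.42, with 8 of 11, 4 of 9 and 4 of 9 lower. Eomes was among the lower genes only in cluster 17.

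The other lists of the whole E14.5 libraries showed higher FGF pathway genes, with a median of 1.03 and Fgf17, Etv5, Spry2 and Etv1 higher among 5, and lower ciliogenesis genes, with a median of -1.37 and 6 of 9 lower. Secreted Wnt antagonists had a median of 0.50, with Sostdc1 and Sfrp1 higher and Dkk3 and Draxin lower. Patterning genes had a median of -0.25, with Zbtb20 (-1.98), Prox1 (-1.47) and Emx2 lower, and intermediate progenitor genes -0.30, with Insm1 higher and Gadd45g and Mfap4 lower. Glutamatergic neuron genes had a median of -0.01, with Neurod2, Neurod6 and Bcl11b higher and Slc17a6, Bhlhe22, Zfpm2 and Crym lower, and pan-neuronal genes -0.19, with Stmn2 and Stmn4 lower. BMP ligands and targets had a median of -0.02, with Bmp4, Bmp5 and Bmp7 higher and Bmp6, Id3 and Msx1 lower. Cell cycle inhibitors and p53 targets had a median of 0.02, with Cdkn1a and Cdkn1c higher and Cdkn1b, Ccng1 and Trp53inp1 lower. Medians were -0.08 for the Notch pathway, -0.04 for the Shh pathway with Cdon lower, 0.15 for S phase with Gmnn higher, 0.02 for G2 and M phase, 0.11 for hypoxia and glycolysis with Hk2 higher and P4ha1 lower, and -0.09 for cell adhesion with Cdh6 and Cdh8 higher. Dissociation and stress genes were lower in 7 of 14 (median -0.56), including Fos at 171 and 63.3 CPM.

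Among genes of at least 50 CPM, the highest ratios in the whole E14.5 gof library, besides Wif1 and Ccnd1, belonged to Tex15, Prkcb (5.65-fold), Mybpc1 (4.39-fold), Asic2, Camk2n1, Col3a1, Sostdc1 and Tagln2 (3.35-fold). Among the lowest were Htr2c (12.8-fold lower), Htra1 (8.96-fold), Tnc (6.94-fold), Reln, Ttr, Hist1h2an, Kcnip1, Rspo2 and Zbtb20 (3.93-fold). Tnc encodes tenascin C, a matrix protein of radial glia.

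Between E11.5 and E14.5 the control libraries differed in neuronal and in signalling genes, and also in the cells they held. Diencephalic-like cells made up 13.99% at E11.5 and 0% at E14.5, and non-neural cells 12.6% and 1.85%. Cluster 1, led by Fgf17 and Fgf8, held 11.7% and 0.0303%. The values below are therefore not shown to change within 1 kind of cell. Glutamatergic neuron genes had a median log2 ratio (E14.5 over E11.5) of 2.70 and pan-neuronal genes of 2.42, with all 15 measured members of each higher, while the median of all genes was 0.62. FGF pathway genes had a median of -2.02 with all 9 lower, and BMP ligands and targets one of -1.23 with 9 of 13 lower and 2 higher. Among genes of at least 50 CPM the highest were Csmd1, Pcp4, Unc5d, Neurod6, a transcription factor of cortical neurons, and Tiam2, and the lowest were Fgf17, Hmga2, an early progenitor factor, Lum, Pf4 and Mest. Cajal-Retzius genes had a median of 1.47 in control and 0.14 in gof, hem genes -0.79 and -1.64, choroid plexus genes 1.07 and 0.52, and Wnt targets 0.64 and 1.31. Reln was 3.68 higher on the log2 scale at E14.5 in control and 1.13 in gof, while Trp73 was at 12.9 CPM in the E11.5 gof library and 2.03 CPM in the E14.5 gof library. Age and library cannot be told apart here, and the difference of the ratios between ages was not tested.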

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

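Of the tests in this part, those on removed barcodes and on Wnt targets in pallial progenitor-like cells were written before their values were seen; those on the reporter share, the Cajal-Retzius markers of cluster 29 and its depth were chosen after. 2 results stood out because the gof library lay on opposite sides of the control at the 2 ages, and neither difference was tested. The log2 ratio of the Cajal-Retzius-like share was 0.42 at E11.5 and -4.34 at E14.5, a difference of -4.76; its E11.5 side turned to -0.38 with the stricter barcode filter and to -0.017 with each library clustered on its own, where E14.5 gave -0.27, on the same side. That of the tdTomato-positive share was -1.04 at E11.5 and 0.23 at E14.5, a difference of 1.27; positive cells of E11.5 had a median of 13454 UMIs in control and 9758.5 in gof, so depth also enters it.

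The smaller share of Cajal-Retzius-like cells in the E14.5 gof library was weighed against 3 explanations. Too few cells of the reporter lineage in the pool is argued against by the tdTomato-positive share, 19.7% in gof and 16.8% in control, and loss in the filters by Trp73, at 1.65 CPM (0.963 to 2.65) in the 954 removed gof barcodes and 25.5 CPM in kept control cells. That the missing cells lie in cluster 29 with their markers intact is argued against by the median log2 ratio of the 13 markers there, -2.15 against control Cajal-Retzius-like cells; cells of that origin with most markers lowered stay open, and at a resolution of 2 part of them take the class's name (log2 ratio of the share 0.16). A candidate explanation is that fewer recombined cells took on or kept a Cajal-Retzius identity, a hypothesis drawn from these same libraries and not itself tested. A difference between the 2 pools of embryos in stage or dissection is untested.

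Cluster 29, rich in reporter and made up of E14.5 gof cells alone, was weighed against 2 explanations. Doublets are argued against by its median UMI count, 1.05 times that of its library. A shift of the whole gof library is argued against only as a general rise of Wnt targets. Within pallial progenitor-like cells their median log2 ratio was -1.34, while the cluster held these genes at high levels. Wnt targets were left out of the clustering, so a library-wide difference in other genes stays open. The cluster may hold recombined cells that keep Wnt targets high and hold part of the markers of Cajal-Retzius neurons, 6 of 13 within 4-fold of control. These values are sums over the whole cluster. At a resolution of 2, reporter-rich cells of the gof library alone fell into clusters of 439 and 279 cells with different names. Whether it is a cell type or a feature of 1 library is untested, since no second gof library of this age exists here.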

How the results depend on the processing

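The alternatives on naming limits, 2000 variable genes, tdTomato-positive cells and the reporter share were chosen after results had been seen; the others were planned. No paired analysis was possible because each group is 1 library from its own pool of embryos. Each alternative value was set against a range around the first value, the 95% limits of 1 library over the opposite limits of the other. This range is wider than a 95% interval of the ratio. For list medians it was the median of the members' limits, which is no interval of the median. Of the alternative values, 230 list medians, 76 shares and 283 single genes stayed within this range and 86, 17 and 151 moved out of it. Another 8, 11 and 6 changed sign from a first value whose range leaves out 0. Sign changes of first values whose range holds 0, such as the Cajal-Retzius list at E11.5, are not among the last. Of the 283 single-gene values, 55 without an expression filter and 55 with at least 50 CPM could not move. Those settings change only which genes enter a list. Except where said, the cause was not tested. All values are log2 ratios of gof over control.

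For shares at E11.5, requiring 2000 genes and at most 5% mitochondrial UMIs turned hem-like cells to 0.10, hem-like or choroid plexus-like cells also to 0.10, and Cajal-Retzius-like cells to -0.38. With 500 genes and 20%, these were -1.04, -1.05 and 0.049. Clustering each library on its own gave 0.47 for hem-like cells, because 527 control cells are then named choroid plexus-like, -0.49 with these joined, and -0.017 for Cajal-Retzius-like cells. A resolution of 0.5 gave -0.025 for hem-like cells and -0.027 with choroid plexus-like cells joined. For Cajal-Retzius-like cells, a resolution of 2 gave 0.071, marker genes kept in the clustering 0.13, the gate of 3 markers per cell 0.12, 2000 variable genes 0.053 and neural cells as denominator 0.61, the last by construction, since non-neural cells were more frequent in gof.

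For shares at E14.5, clustering each library on its own gave 1.248 for choroid plexus-like cells, 0.16 with hem-like cells joined and -0.27 for Cajal-Retzius-like cells. The gate gave 0.067, -0.72 and -1.39. Naming without a minimum score gave 0.81 and 0.80 for choroid plexus-like cells alone and joined, because cluster 29 then takes that name. A resolution of 2 gave 0.16 for Cajal-Retzius-like cells, because a cluster of gof cells alone takes the name. The tdTomato-positive share at E14.5 was 0.63 with at least 4 UMIs; at E11.5 it was -1.39 with at least 4, -0.50 with at least 1 and -0.57 in thinned cells.

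For list medians at E11.5, genes of at least 50 CPM gave -0.23 for Wnt targets (7 members) and -0.37 for stress genes (5 members). No expression filter gave 0.36 for Wnt targets, -0.032 for choroid plexus, -0.33 for hem and 0.031 for adhesion genes. The mean of the CPM of each cell gave 0.25 for Wnt targets. Neural cells gave 0.30 for Wnt targets, 0.40 for Cajal-Retzius, -0.0046 for choroid plexus, -0.20 for hem, -0.16 for stress and 0.021 for hypoxia genes. In tdTomato-positive cells Wnt targets were at 1.13, Cajal-Retzius genes at 0.48, hem genes at -0.56, hypoxia genes at 0.049 and adhesion genes at 0.046.

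At E14.5, Wnt targets were at 0.89 with TMM, 0.76 with a pseudocount of 10 CPM, 0.70 without an expression filter and 1.99 in tdTomato-positive cells. Cajal-Retzius genes were at -0.84 with that pseudocount and -1.66 in tdTomato-positive cells. Choroid plexus genes were at -0.66 with it, -0.88 without a filter, -1.26 in neural cells and -1.90 in tdTomato-positive cells, and hem genes at -0.96 with it, -1.55 with the mean of cells and -1.79 in tdTomato-positive cells. Intermediate progenitor genes turned to 0.36 in tdTomato-positive cells. Among single genes, tdTomato-positive cells turned Ctnnb1 to 0.11 at E11.5 and 0.19 at E14.5, Axin2 to 0.62 and tdTomato itself to 0.34 at E11.5, and Lef1 to 1.18 at E14.5. Neural cells turned Axin2 to 0.038 at E11.5. The tdTomato-positive cells were chosen by their tdTomato UMIs, and at E11.5 had a median of 9758.5 UMIs in gof and 13454 in control. The tdTomato ratio within them is therefore no measure of reporter expression.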

Other observations

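The test of the tdTomato level in pallial cells was chosen after the result was seen, and the test within pallial clusters was written after the value of the whole class was known; the clusters named here were also picked after their sizes had been seen. In the E14.5 libraries a cluster named glutamatergic neuron-like, led by Npy, a neuropeptide, and Scg2, a granule protein, held 146 control and 4 gof cells. It scored 0.74 for that class and 0.64 for intermediate progenitor, with none of the class's markers among its leading genes. At a resolution of 2 a cluster also led by Npy and Scg2, with 220 control and 5 gof cells, stayed unnamed. Control cells of the named cluster carried tdTomato at 86.8 CPM (75.2 to 99.6), against 15.1 to 43.1 CPM in the other glutamatergic neuron-like clusters. The class as a whole had a share of 27.7% in both libraries at the resolution of 1, which was not kept at 2. The Cajal-Retzius-like cells of E11.5, taken as a class, had higher FGF pathway genes in gof, with a median of 0.74 and Spry2, Etv1 and Dusp6 higher. BMP genes were lower there, with a median of -0.50 and Id1, Id3, Bmp5 and Bmp7 lower and Msx1 higher. Ciliogenesis genes had a median of -0.54 with Mcidas and Ccno, which drive multiciliated cells, and Tekt1 lower. The make-up of the class differed too: at a resolution of 2 the cluster led by Lhx1, Trp73, Ccno and Mcidas held 311 control and 352 gof cells, and that led by Uncx and Ebf2 held 387 and 669, so these lower values are not shown to lie within 1 kind of cell.

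Between ages in the gof libraries, glutamatergic neuron genes had a median of 2.58 and pan-neuronal genes of 2.02, with the median of all genes at 0.60. Their Wnt ligands and R-spondins had a median of -1.64, and FGF pathway genes one of -1.35 with 9 lower.

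Pallial progenitor-like cells of E14.5 were spread differently over clusters: cluster 17 held 1463 control and 218 gof cells and cluster 19 held 197 and 867, while cluster 20 was shared (1252 and 970), and Wnt targets were lower in gof. Recombined cells as the bulk of cluster 19 are argued against by its tdTomato level, 25.6 CPM (22.8 to 28.7), far under the 285 CPM of choroid plexus-like gof cells, a comparison added after a first one with non-neural cells (20.7 CPM, 15.9 to 26.4) had overlapping intervals; a small recombined part stays open. A different spread over clusters 17, 19 and 20 alone is argued against by the Wnt target medians within them, the highest of which was -0.70. Make-up within these clusters stays open. At a resolution of 2, pallial progenitor-like clusters differed strongly between the libraries, one with 896 control and 35 gof cells and another with 83 and 541. A difference between the libraries alone cannot be told apart from one between kinds of cell: the ratios of cluster 19 to cluster 17 in control and in gof correlated at 0.879 across 3854 genes, but both clusters come from a joint clustering, which makes such a correlation. Another part of the pallium in the dissected pools cannot be told apart either with 1 pool per group, the patterning median being -0.40, and less Wnt signal from a hem with fewer ligands is untested.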
